A study of Mus musculus with 36 samples.

How the data were processed

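RNA was measured in 36 libraries of plasma cells sorted from mouse bone marrow, 2000 cells per library, in 8 groups of 2 cohorts. Per the labels' protocols, cDNA was made with an oligo-dT primer and a template switch, amplified, and cut and tagged with Nextera XT. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, quantified with Salmon 1.3.0 on the mouse build GRCm38 and tested with DESeq2 1.32.0. The deposited tables, 1 per library, give estimated counts for 140825 transcripts, which the authors obtained with Salmon and which are expected counts, not whole numbers. They also give TPM (Salmon's length-scaled shares, which the authors' run normalized within each library), and 2 lengths per transcript, per the file headers. The deposited effective lengths were identical in all 36 libraries, and for 90.3% of transcripts the length exceeded the effective length by 250 bases.

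Estimated counts were summed to genes with the GENCODE mouse annotation, release 21, on GRCm38. Of the transcripts, 139960 matched and 865 did not, and the latter held 0.0636% to 0.134% of reads. This gave 54203 genes, 426 of them immunoglobulin genes, and totals of 54.1 to 97.6 M reads per library. No strand information was used, so reads of overlapping and antisense genes cannot be told apart, and values within families of near-identical genes (MHC class I, Gbp, Ly6, Rhox4, Serpina3 and immunoglobulin genes) are uncertain. The labels describe no molecular identifiers, so PCR copies stay in the read numbers.

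Groups were taken from the labels. Gene sums were rounded and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold; all tests of genes and lists were two-sided. For 12 comparisons within a cohort, 1 fit held the 18 libraries of that cohort (15323 genes in cohort D and 15416 in cohort M), and for 4 comparisons across cohorts a fit held all 36 (17116 genes). The 32 gene lists, 21 of pathways and 11 of cell types, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and, as an alternative, an estimated correlation. A list needed 3 measured members, and p-values were adjusted over the lists of a comparison. Immunoglobulin shares were compared by exact two-sided permutation, whose smallest p is 0.0286 for 4 against 4 libraries and 0.00952 for 6 against 4. Shared calls between cohorts were tested with Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for sums, permutations and plots.

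Named genes followed a rule. In the 6 comparisons of a transgenic group with its control these were the 3 targeted genes, the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 3, and up to 4 members with the smallest p from each list with a camera call or at least 3 called members. The other 10 comparisons named 4 genes per direction. A few genes that the rule names are not reported. Unnamed gene models, immunoglobulin and T cell receptor V, D and J segments, Y-linked genes and Xist were left out of this choice. For a gene with 0 to 3 reads in a group the level or the summed reads are given in place of a fold change, and list medians were also computed with such members at the level of 3 reads.

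The test was tried on simulated counts with 200 changed genes, 100 at each fold. These were drawn only from genes above a minimum mean CPM, so recovery among genes of lower level was not simulated. For Ikk2ca(D) against Control(D), 32% of 2-fold and 92% of 4-fold changes were recovered among 14605 genes, with 4.62% false calls. For Ccnd1-Ikk2ca against Control(D) these were 42%, 95% and 5.52% (14560 genes), for Ikk2ca(M) against Control(M) 32%, 84% and 3.33% (14482 genes), and for MMSET-Ikk2ca against Control(M) 34%, 93% and 6.62% (14601 genes). The groups, tests, gene lists, rule for named genes and the following alternatives were chosen before the data were examined: DESeq2 1.42.0, DESeq2 size factors in edgeR, limma voom with quality weights, no low-count filter, immunoglobulin genes left out, a transcript length offset, the replicate number as a block, the pairs limited to replicates 1 to 4, all 36 libraries in 1 fit, fits of only the groups compared, each library left out in turn, an adjusted p of 0.01 for shared calls, and TPM for the targeted genes and immunoglobulin shares. Xist as a covariate, and Y-linked genes with Xist left out, were added after the data were seen.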

Results

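Plasma cells, the antibody-secreting end stage of the B cell lineage, were sorted from mouse bone marrow by a reporter signal and by the surface proteins CD138 and TACI, and their polyadenylated RNA was sequenced. The 36 libraries formed 2 cohorts of 18, each with a control, 2 groups with 1 transgene and a group with both. In cohort D these were Control(D), Ccnd1 and Ikk2ca(D), with 4 libraries each, and Ccnd1-Ikk2ca with 6. In cohort M they were Control(M), MMSET and Ikk2ca(M), again with 4 libraries each, and MMSET-Ikk2ca with 6. The series concerns mouse models of subgroups of multiple myeloma, a cancer of plasma cells, and the design asks what each transgene and each pair did to plasma cell expression. Each library was estimated at 54.1 to 97.6 M reads. Of these 43.9% to 73.0% came from immunoglobulin genes, leaving 16.2 to 34.9 M reads for all other genes. Between 12297 and 14045 genes had at least 10 reads per library. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples. Levels are counts scaled to library size (CPM), given as mean ± SD over the libraries of a group, and log2 fold changes carry a standard error (SE). This SE was derived from the edgeR test, as the absolute log2 fold change divided by the square root of its F statistic. The levels of the 3 targeted genes set side by side over 8 groups were scaled over all 36 libraries, and other levels within the cohort.

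Ccnd1 encodes cyclin D1, which drives the G1 phase of the cell cycle (chromosome 7, 144929931 to 144939925, GRCm38). It stood at 0.838 ± 0.301 CPM in Control(D), 302 ± 55.2 in Ccnd1, 1.39 ± 1.44 in Ikk2ca(D) and 705 ± 254 in Ccnd1-Ikk2ca. It lay between 0.185 and 0.740 in the groups of cohort M. Nsd2, the mouse gene for the histone H3K36 methyltransferase MMSET (chromosome 5, 33820725 to 33897975), stood at 3.31 ± 1.19 CPM in Control(M), 622 ± 184 in MMSET, 4.17 ± 1.71 in Ikk2ca(M) and 341 ± 165 in MMSET-Ikk2ca. It lay between 2.85 and 6.43 CPM in cohort D. Ikbkb, which encodes the NF-kB activating kinase IKK2 (chromosome 8, 22659212 to 22706589), stood at 27.2 ± 8.23 CPM in Control(D) and 26.5 ± 7.58 in Control(M). Its level was 57.1 ± 17.5 in Ikk2ca(D), 53.3 ± 6.42 in Ccnd1-Ikk2ca, 56.9 ± 10 in Ikk2ca(M) and 54.4 ± 6.66 in MMSET-Ikk2ca. Against the cohort's control, Ikbkb rose by 1.06 on the log2 scale in Ikk2ca(D) (SE 0.230, adjusted p = 0.0451), by 0.96 in Ccnd1-Ikk2ca (adjusted p = 0.00781) and by 1.02 in MMSET-Ikk2ca (adjusted p = 0.0125). The 1.08 in Ikk2ca(M) missed the threshold (adjusted p = 0.0532). The deposited tables list mouse reference transcripts and no transgene as a separate sequence, so transgene and endogenous transcripts of these genes cannot be separated.

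**Figure D1:**
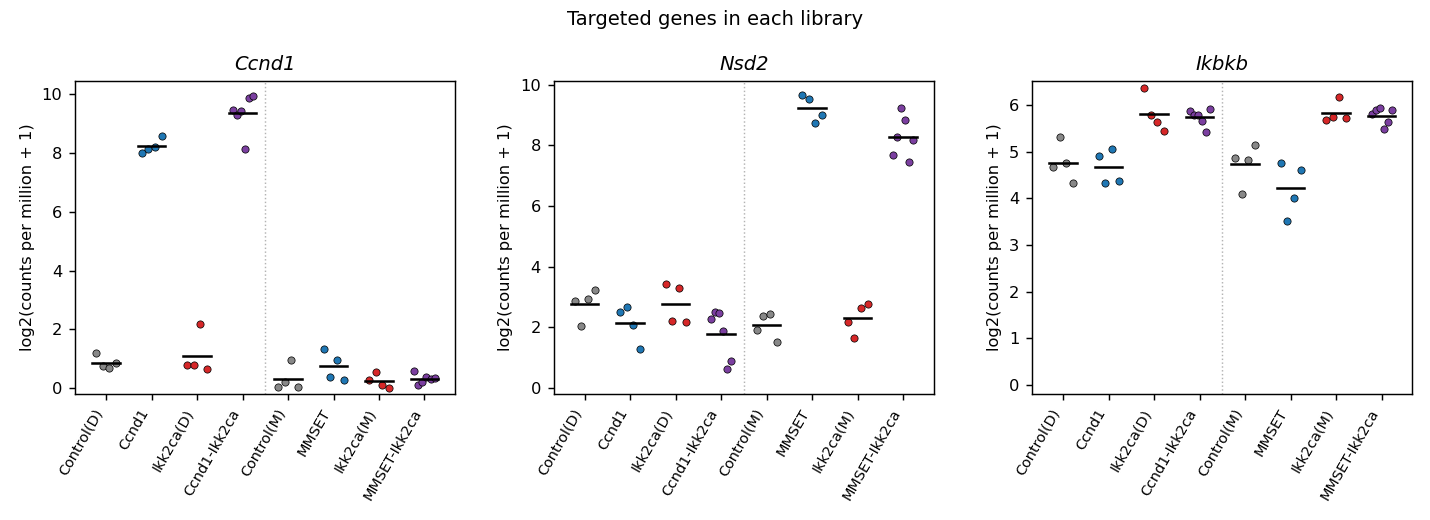
Levels of Ccnd1, Nsd2 and Ikbkb in each of the 36 libraries, as log2(CPM + 1), by group. Points are libraries and bars are means on that scale. Ccnd1 averaged 302 and 705 CPM in the 2 groups that carry it and Nsd2 622 and 341 CPM in its 2 groups, while Ikbkb averaged 53.3 to 57.1 CPM in the 4 Ikk2ca groups and 18.8 to 27.2 CPM in the others.

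The Ccnd1 transgene alone moved few genes beyond the spread between libraries. Ccnd1 itself was the 1 gene called among 15323 (log2 fold change 8.49, SE 0.696, adjusted p = 2.4e-05). The list of the 3 targeted genes holds the transgenes themselves, so its calls check the labels and no pathway. It passed in Ccnd1 (camera adjusted p = 0.0258, adjusted p = 0.285 with an estimated correlation), Ccnd1-Ikk2ca (0.0192 and 0.0664), MMSET (0.00824 and 0.16) and MMSET-Ikk2ca against Control(M) (0.000811 and 0.0371) and Ikk2ca(M) (0.00626 and 0.0962). MHC class II genes, whose products present antigen to helper T cells, had lower values, with H2-Ab1 at 177 ± 60.3 CPM against 359 ± 171 in Control(D) and H2-Eb1 at 78.3 ± 35.1 against 171 ± 70.5 (n = 4 each). None of the 10 measured class II genes fell over all genes, 3 did when adjusted over the list alone, and their median of -1.16 gave a camera adjusted p of 1.68e-05 (adjusted p = 0.285 with an estimated correlation). The mean of the class II list lay below all Control(D) libraries in 2 of 4 Ccnd1 libraries. Neutrophil markers had higher values, with a median of 1.85 over 13 genes, 0 of them called (camera adjusted p = 0.000139, adjusted p = 0.504 with an estimated correlation). S100a9, a neutrophil calcium-binding protein, stood at 123 ± 92.8 CPM against 32.2 ± 25.6. Oxidative phosphorylation genes had a median of 0.17 (31 genes, 0 called; camera adjusted p = 0.000512, adjusted p = 0.504 with an estimated correlation), with Cox5b of complex IV at 46.5 ± 2.46 against 35.5 ± 1.67 CPM. Stress and immediate-early genes had a median of 0.84 (15 genes, 0 called; camera adjusted p = 0.00667, adjusted p = 0.285 with an estimated correlation). Besides the 1 call from edgeR, 963 genes had an unadjusted p under 0.05, DESeq2 called 142 and limma voom 0. The count was 2 without Control(D) 1, 3 without Control(D) 4 and 5 with only the 2 groups in the fit.

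In Ikk2ca(D), 61 genes rose and 6 fell against Control(D), 55 of the 67 by at least 2-fold. Elf3, an ETS transcription factor of epithelial cells, reached 7.02 ± 4.87 CPM against 0.0120 ± 0.0239. Ncan, which encodes the proteoglycan neurocan, rose from 0.597 ± 0.562 to 111 ± 56.9 CPM (log2 fold change 7.53, SE 1.14, adjusted p = 0.0102). Also among the largest rises were Cp (ceruloplasmin, log2 fold change 4.04), the cell cycle inhibitor Cdkn1a (p21, 3.60 ± 0.485 SE, adjusted p = 0.00248), the folate hydrolase Ggh (3.54), the interferon-inducible Ifi211 (2.98), the glycosyltransferase Large2 (2.95) and the protease inhibitor Serpina3f (2.86). Of the named falls, H2-Ab1 and H2-Eb1 dropped by 2.28 and 2.02 on the log2 scale, the protease cathepsin E gene Ctse by 1.99, the octamer-binding factor Pou2f1 by 1.44 and the polyamine acetyltransferase Sat1 by 0.70.

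Of 49 measured NF-kB pathway and target genes, 4 rose and 0 fell in Ikk2ca(D) (7 and 0 when adjusted over the list alone), and 45 did not pass the test. Icam1, an adhesion molecule, went from 26.0 ± 8.23 to 119 ± 35.4 CPM (log2 fold change 2.2, SE 0.305, adjusted p = 0.00248) and Tnfaip3, which encodes the NF-kB feedback inhibitor A20, from 22 ± 8.57 to 115 ± 44.0 (2.38, adjusted p = 0.00449). The NF-kB subunit gene Relb rose by 1.35 and Tnip1, whose product binds A20, by 0.77. As a set the list did not pass (median 0.21, camera adjusted p = 0.0818). Of 18 p53 target genes, Cdkn1a and Ccng1 (cyclin G1, 1.0) rose and none fell (6 and 0 when adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.000473, adjusted p = 0.0518 with an estimated correlation). MHC class II genes fell in 2 of 10 (7 over the list alone). Their median was -2.17 (camera adjusted p = 1.88e-06, adjusted p = 0.179 with an estimated correlation), and the list's mean lay below all Control(D) libraries in 3 of 4 Ikk2ca(D) libraries. Of 15 MHC class I and immunoproteasome genes, B2m, the class I light chain, rose from 2424 ± 261 to 4596 ± 354 CPM and 14 did not pass (5 over the list alone). The median was 0.48 (camera adjusted p = 0.000159, adjusted p = 0.269 with an estimated correlation). The complex III gene Uqcrq rose by 0.80 among 31 oxidative phosphorylation genes (5 over the list alone; median 0.21, camera adjusted p = 0.00206, adjusted p = 0.379 with an estimated correlation).

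Other lists moved as sets in Ikk2ca(D) with few single calls, most of them down. Mitosis genes had a median of -0.62 with 0 of 30 called (camera adjusted p = 0.00129, adjusted p = 0.418 with an estimated correlation), and the anaphase activator Cdc20 stood at 6.76 ± 3.29 against 16.6 ± 7.70 CPM. Medians were -0.23 over 13 H3K36 and H3K27 methylation enzymes, with Ezh2 at 6.24 ± 0.175 against 13 ± 5.75 CPM, and -0.17 over 27 plasma cell identity genes, with 0 called in either (1 and 0 lower over each list alone; camera adjusted p = 0.0404 for both, adjusted p = 0.179 with an estimated correlation). B cell markers had a median of -0.51, with Ly6d the 1 of 27 that rose (1.73, adjusted p = 0.0362; 1 higher and 1 lower over the list alone; camera adjusted p = 0.0462, adjusted p = 0.269 with an estimated correlation). T cell markers had a median of -1.18 with 0 of 10 called (camera adjusted p = 0.0462, adjusted p = 0.264 with an estimated correlation). Stress and immediate-early genes had a median of 0.87 with 0 of 15 called (1 higher over the list alone; camera adjusted p = 0.0462, adjusted p = 0.269 with an estimated correlation). Xist, the RNA that silences an X chromosome in female cells, exceeded 10 CPM in 4 of 4 Ikk2ca(D) libraries and in 1 of 4 Control(D) libraries, and with Xist as a covariate 3 genes were called. DESeq2 called 687 (472 higher, 215 lower), limma voom 127 (75 and 52) and a fit of all 36 libraries 115 (105 and 10). The count was 33, 17 and 31 without Control(D) 1, 2 and 3, 120 without Ccnd1 4, and 107 and 26 without Ikk2ca(D) 1 and 2.

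With both transgenes, 1708 genes differed between Ccnd1-Ikk2ca and Control(D), 893 higher and 815 lower, 1070 of them by at least 2-fold. The named rises were Elf3 (34.8 ± 23.9 CPM), Ccnd1, Ncan (243 ± 110 CPM, log2 fold change 8.66), the kappa-casein gene Csn3 (7.25, from 3.08 ± 1.86 to 470 ± 132 CPM), the homeobox gene Rhox4b (6.62), Enpp5 (6.03), the sphingolipid desaturase Degs2 (6.02) and Cp (5.84, to 1057 ± 478 CPM). Among the falls were Prf1, which encodes the pore-forming protein perforin (22.7 ± 10 to 0.0678 ± 0.139 CPM), the inhibitory receptor Tigit (-5.63), the class II alpha chain H2-Aa (-5.01), Anxa2 (annexin A2, -4.69), the PI3-kinase regulator Pik3r5 (-4.57), the dynamin Dnm3 (-4.52) and the IgM receptor Fcmr (-4.48).

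Plasma cell identity genes fell in 8 of 27 measured and rose in 2 (11 and 2 when adjusted over the list alone). Jchain, which joins polymeric IgM and IgA (chromosome 5, 88519809 to 88527891), fell by 2.97 on the log2 scale, from 72100 ± 18100 to 9200 ± 4980 CPM (SE 0.47, adjusted p = 0.00134). The transcription factor Bhlha15, also called Mist1, fell by 0.98 (adjusted p = 0.00047), the endoplasmic reticulum chaperone Mzb1 by 1.59 and the homing receptor Ccr10 by 4.01. The list's median was -0.42 (camera adjusted p = 0.00109, adjusted p = 0.0247 with an estimated correlation). B cell identity genes fell in 11 of 27 and rose in 1 (15 and 1 over the list alone), with a median of -2.61 (camera adjusted p = 2.27e-07, adjusted p = 0.0174 with an estimated correlation). Cd79a, a signalling chain of the B cell receptor (chromosome 7, 24897381 to 24902197), went from 590 ± 119 to 81.5 ± 23.7 CPM (-2.86, SE 0.239, adjusted p = 2.97e-06). Vpreb3 fell by 2.26 and the early B cell factor Ebf1 by 3.07, while Ly6d rose by 1.91. MHC class II genes fell in 9 of 10 and rose in 1, over all genes and over the list alone. The list's median was -3.12 (camera adjusted p = 2.27e-07, adjusted p = 0.0664 with an estimated correlation). H2-Eb1 and H2-Ab1 fell by 3.13 and 3.11, and H2-Oa went from 5.86 ± 5.58 to 0.00207 ± 0.00508 CPM. Of 15 MHC class I and immunoproteasome genes, 10 rose and 0 fell (11 and 0 over the list alone), among them the proteasome activators Psme2 (1.11) and Psme1 (0.91), B2m (0.92) and the peptide transporter Tap1 (0.73). Their median was 0.78 (camera adjusted p = 1.37e-06, adjusted p = 0.148 with an estimated correlation).

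NF-kB genes rose in 9 of 49 and fell in 2 (12 and 5 over the list alone), with a median of 0.22 that did not pass as a set (camera adjusted p = 0.337). Icam1 rose by 2.87 (SE 0.301, adjusted p = 2.05e-05), Tnfaip3 by 2.69, the inhibitor gene Nfkbia by 1.02 and Tnip1 by 0.81. Of 18 p53 targets, 7 rose and 1 fell (11 and 2 over the list alone), with Cdkn1a at 44.6 ± 11.8 against 2.48 ± 0.596 CPM (4.17, SE 0.484, adjusted p = 5.18e-05), Ccng1 at 1.31, the death effector Bax at 0.77 and Btg2 at 0.75. As a list they had a median of 0.85 (camera adjusted p = 0.000833, adjusted p = 0.0247 with an estimated correlation). Apoptosis regulators rose in 4 of 18 and fell in 0 (5 and 1 over the list alone; camera adjusted p = 0.321), with the pro-death genes Bax, Bcl2l11 (2.34) and Bbc3 (0.87) beside the survival gene Mcl1 (1.60). Oxidative phosphorylation genes rose in 17 of 31 and fell in 0 (22 and 0 over the list alone), with Cox5b at 0.68, the complex I genes Ndufa1 at 0.93 and Ndufb3 at 0.68, and Uqcrq at 0.69. These genes had a median of 0.44 (camera adjusted p = 5.98e-07, adjusted p = 0.158 with an estimated correlation). DNA replication genes rose in 3 of 31 (Tk1 0.79, Cdc45 1.28, Mcm5 1.55) and the histone mRNA binding gene Slbp fell by 0.77 (3 and 1 over the list alone; camera adjusted p = 0.113). On the D-type cyclin and RB axis, Cdkn1a, the CDK4/6 inhibitor Cdkn2c (1.03) and Ccnd2 (cyclin D2, 2.94, to 761 ± 333 CPM) rose and E2f4 fell by 0.79 (3 and 1 of 20, over all genes and over the list alone; camera adjusted p = 0.464).

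Adhesion and migration genes fell in 12 of 27 and rose in 0 (15 and 1 over the list alone), with vimentin (Vim) at -2.87, the homing factor Klf2 at -6.26 (0.118 ± 0.130 against 9.31 ± 1.71 CPM), the chemokine receptor Cxcr3 at 0.0366 ± 0.0719 against 12.8 ± 7.24 CPM and the beta-2 integrin Itgb2 at -1.0. Over the list the median was -1.0 (camera adjusted p = 5.98e-07, adjusted p = 0.0174 with an estimated correlation). Histone methylation enzymes fell in 3 of 13 (5 over the list alone), namely Nsd3 (-0.63), Nsd1 (-0.81) and Kdm2a (-0.63), with a median of -0.57 (camera adjusted p = 0.00535, adjusted p = 0.0296 with an estimated correlation). Interferon-stimulated genes rose in 8 of 29 and fell in 1 (8 and 2 over the list alone; median 0.16, camera adjusted p = 0.351), among them the guanylate-binding genes Gbp3 (2.85) and Gbp7 (2.94), the GTPase Igtp (1.79) and the nucleic acid sensor Zbp1 (1.10). Of 18 immune interaction ligands, 5 rose, with Cd274 (PD-L1) at 1.42 and the galectin Lgals9 at 1.55, and 2 fell, Cd48 at -1.65 and Cd200 at -4.88 (7 and 2 over the list alone; median -0.10 while the test pointed up, camera adjusted p = 0.66). Secretory pathway genes rose in 2 of 31 and fell in 1 (0 and 0 over the list alone; camera adjusted p = 0.897): Sec61a1 0.35, Sel1l 1.13 and Syvn1 -0.38.

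Markers of several other cell types were lower beside these groups in Ccnd1-Ikk2ca. Basophil, eosinophil and mast cell markers had a median of 1.10 (camera adjusted p = 0.66) and stromal and endothelial markers 1.13 (camera adjusted p = 0.897), with 0 of 4 called in each. Neutrophil markers had a median of -2.40 with 1 of 13 fallen, Elane at 0.00464 ± 0.00723 against 1.33 ± 1.84 CPM (camera adjusted p = 3.23e-05, adjusted p = 0.26 with an estimated correlation). T cell markers had a median of -2.54 with Cd3g the 1 of 10 that fell, at 0.00253 ± 0.00619 against 7.10 ± 5.62 CPM (camera adjusted p = 0.00674, adjusted p = 0.0664 with an estimated correlation). Of 14 monocyte and macrophage markers, Adgre1 fell to 0.00207 ± 0.00508 from 3.36 ± 2.91 CPM and Ctss rose by 0.86, close to the threshold. The list had a median of -1.64 (camera adjusted p = 0.0321, adjusted p = 0.267 with an estimated correlation). Of 4 measured B cell precursor markers, 3 fell: Ebf1, Cd93 (-1.59) and Vpreb1, at 0 in Ccnd1-Ikk2ca and 0.143 ± 0.165 CPM in Control(D). Its members had a median of -3.03 (camera adjusted p = 0.00788, adjusted p = 0.0664 with an estimated correlation). The count of called genes was 2806 with DESeq2 and 2377 with limma voom (1172 higher, 1205 lower), and 1124 without Control(D) 1 and 984 without Control(D) 2.

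Against the single transgenes, Ccnd1-Ikk2ca differed from Ikk2ca(D) in 65 genes (8 higher, 57 lower) and from Ccnd1 in 950 (430 higher, 520 lower). The balance against Ikk2ca(D) was 173 higher and 312 lower with DESeq2, 45 and 71 with limma voom, and 5 and 4 with only the 2 groups compared. With the replicate number as a block the counts were 37 and 551, and with the pairs limited to replicates 1 to 4 they were 16 and 544. The balance against Ccnd1 was 515 higher and 383 lower with all 36 libraries, and 449 and 366 with only the 2 groups compared. Over Ikk2ca(D), Ccnd1 rose by 8.98, the circadian gene Noct by 1.78, the actin gene Actg1 by 1.69 and the linker histone Hist1h1c by 1.05. The named falls were Myo1e (-3.42), the sodium pump subunit Atp1b1 (-3.27), Jakmip1 (-3.06) and the calcium channel Itpr1 (-2.70). B cell identity genes were lower in Ccnd1-Ikk2ca than in Ikk2ca(D) (1 of 27 fell, 9 over the list alone). Their median was -1.60 (camera adjusted p = 7.94e-09, adjusted p = 0.00694 with an estimated correlation). Adhesion and migration genes were lower as well (1 fell, 10 over the list alone). The median was -0.55 (camera adjusted p = 3.86e-08, adjusted p = 0.00694 with an estimated correlation). Mitosis genes had a median of 0.78 (0 called; camera adjusted p = 3.86e-08, adjusted p = 0.327 with an estimated correlation). Over Ccnd1, the immunoglobulin transporter Pigr rose to 19.8 ± 13.3 from 0.0352 ± 0.0265 CPM, Tsc22d1 by 7.37, Elf3 by 7.30 and Rhox4b to 15.5 ± 11.9 from 0.0119 ± 0.0145 CPM. Prf1, Tigit (-5.69), Fcrl1 (-4.67) and the interleukin-2 receptor chain Il2rb (-4.55) fell. Plasma cell identity genes fell in 9 of 27 against Ccnd1 (10 over the list alone). The list's median was -0.39 (camera adjusted p = 3.55e-05, adjusted p = 0.0129 with an estimated correlation). Other lists that passed with an estimated correlation against Ccnd1 were B cell identity (4 of 27 fell; median -2.21, camera adjusted p = 4.84e-06, adjusted p = 0.0229 with an estimated correlation) and p53 targets (4 of 18 rose and 1 fell; median 0.63, camera adjusted p = 0.000653, adjusted p = 0.0229 with an estimated correlation). Adhesion and migration genes did too (11 of 27 fell and 1 rose; median -1.02, camera adjusted p = 2.45e-06, adjusted p = 0.0129 with an estimated correlation). Neutrophil markers fell in 4 of 13 (12 over the list alone). As a list they had a median of -4.27 (camera adjusted p = 5.75e-11, adjusted p = 0.114 with an estimated correlation). The interaction asked whether the pair departed from the sum of the single log2 effects, and 4 genes passed, all lower than that sum: Cd79a (-2.12, SE 0.351, adjusted p = 0.031) and, named after their values were seen, Prkcb (-7.79), Pltp and Gpr174. Pltp had 1 read in Ccnd1-Ikk2ca and 1365 in Control(D), and Gpr174 had 1 and 1146. DESeq2 called 153 genes for this interaction, 57 higher and 96 lower, and limma voom 2. With edgeR 0 genes passed, Cd79a included, when the pairs were limited to replicates 1 to 4, with all 36 libraries in 1 fit and with Xist as a covariate, and 1051 had an unadjusted p under 0.05 in the fit with 4 calls. Against Ikk2ca(D) the count fell to 9 with only the 2 groups in the fit, was 485 with DESeq2, and ranged from 15 without Ccnd1-Ikk2ca 4 to 120 without Ccnd1-Ikk2ca 2, with 13 of 18 libraries moving it by over 1.5 times. Against Ccnd1 it was 410, 562 and 521 without Ccnd1 1, 2 and 3. The interaction count ranged from 0 without Control(D) 2 or Ccnd1-Ikk2ca 2 to 7 without Ccnd1-Ikk2ca 3, moving by over 1.5 times in 10 of 18 cases.

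**Figure D2:**
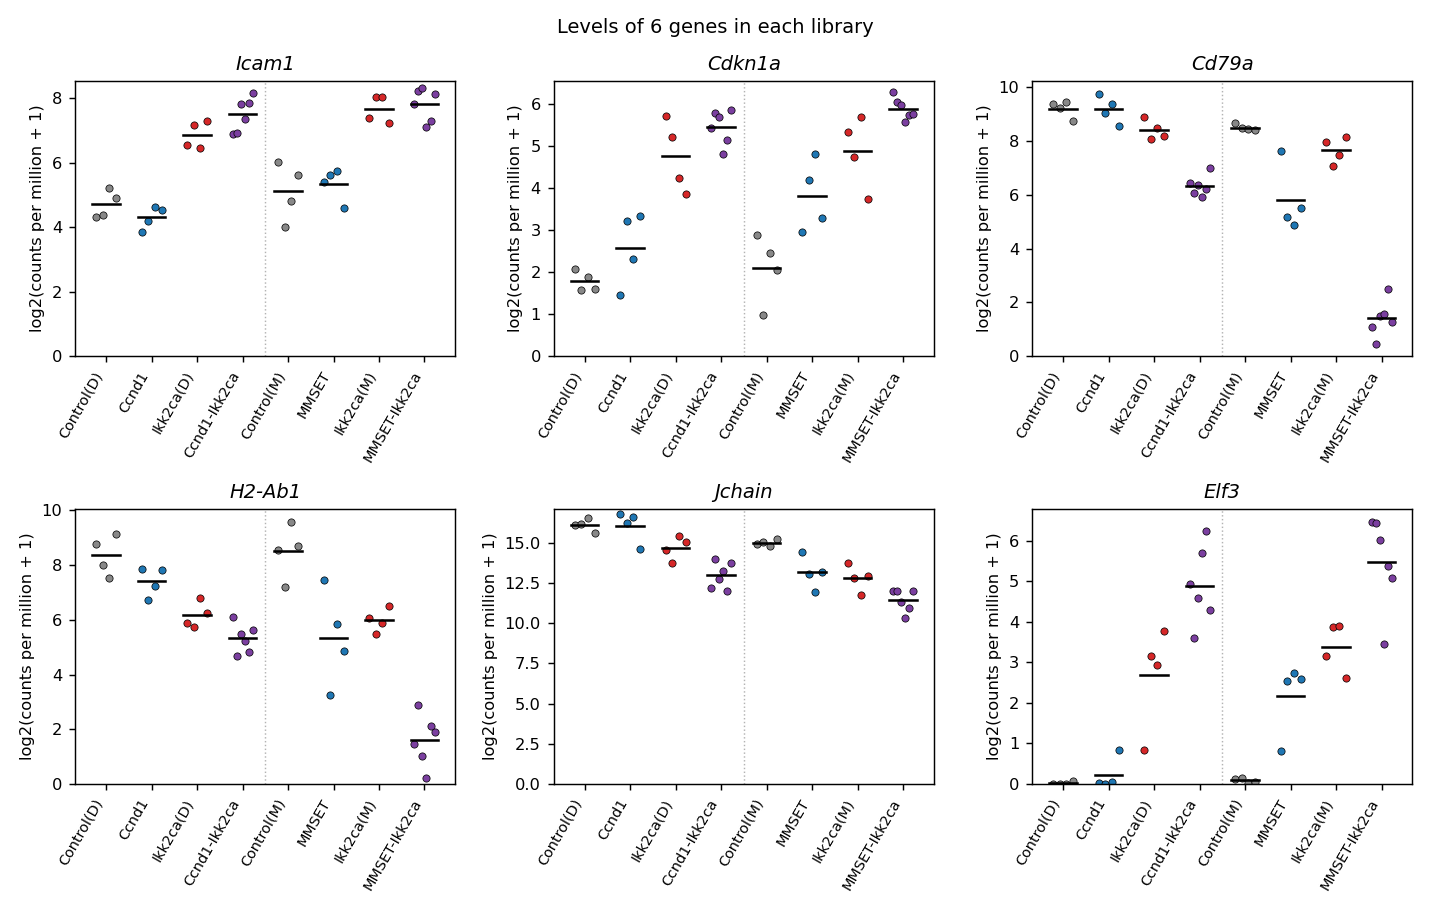
Levels of Icam1, Cdkn1a, Cd79a, H2-Ab1, Jchain and Elf3 in each of the 36 libraries, as log2(CPM + 1), by group. Points are libraries and bars are means on that scale. Cd79a averaged 81.5 CPM in Ccnd1-Ikk2ca and 1.91 CPM in MMSET-Ikk2ca, against 590 and 359 CPM in the controls.

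The MMSET transgene alone changed 100 genes against Control(M), 73 higher and 27 lower, 86 by at least 2-fold. Slc7a11, the cystine transporter that feeds glutathione synthesis, went from 0.0247 ± 0.0169 to 9.94 ± 5.51 CPM (log2 fold change 8.56, SE 0.742, adjusted p = 4.08e-06) and Nsd2 from 3.41 ± 1.23 to 640 ± 194 (7.55, SE 0.515, adjusted p = 3.67e-07). Fam174b (7.54), the interferon-induced Ifi44 (7.19), Elf3 (5.92), the transglutaminase Tgm2 (5.51), Rhox4b (4.93) and the arrestin family gene Arrdc4 (4.10) rose. The named falls were Ms4a1, which encodes the B cell protein CD20 (-2.21), the heme oxygenase Hmox1 (-2.13), the syndecan Sdc4 (-1.99), Ralgds (-1.85), the lysosomal channel Tmem175 (-1.73), the superoxide dismutase Sod1 (-1.50), the myosin Myo5a (-1.43) and the polysialyltransferase St8sia4 (-1.36).

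B cell identity genes fell in 1 of 26 in MMSET (7 over the list alone), with Cd79a at 76.0 ± 80.5 against 359 ± 28.4 CPM, which did not pass. These genes had a median of -1.87 (camera adjusted p = 2.26e-06, adjusted p = 0.16 with an estimated correlation). No class II gene was called over all 15416 genes, while 7 of 10 fell and Cd74, the invariant chain, rose over the list alone, at 6326 ± 991 against 4038 ± 948 CPM. Over the list the median was -2.08 (camera adjusted p = 0.00033, adjusted p = 0.335 with an estimated correlation), and the list's mean lay below all Control(M) libraries in 1 of 4 MMSET libraries. Of 29 interferon-stimulated genes, Ifi44 and Zbp1 (1.24) rose (4 over the list alone; median 0.63, or 0.58 without the 1 member at 0 to 3 reads in both groups, camera adjusted p = 0.00176, adjusted p = 0.335 with an estimated correlation). The p53 targets Zmat3 (1.80) and Btg2 (0.87) were the 2 of 19 that rose (5 over the list alone). The list had a median of 0.53 (camera adjusted p = 0.0355, adjusted p = 0.335 with an estimated correlation). Secretory pathway genes had 0 of 31 called and 10 higher over the list alone, with the chaperone-associated Creld2 at 1290 ± 345 against 726 ± 111 CPM. Its members had a median of 0.29 (camera adjusted p = 0.000699, adjusted p = 0.335 with an estimated correlation). Class I genes likewise had 0 called and 8 higher over the list alone. Their median was 0.43 (camera adjusted p = 0.000309, adjusted p = 0.335 with an estimated correlation). DNA replication genes had a median of 0.51 with 0 called (camera adjusted p = 0.00206, adjusted p = 0.424 with an estimated correlation). Mitosis genes had a median of 0.79 with 0 called (camera adjusted p = 0.0321, adjusted p = 0.742 with an estimated correlation). MYC targets had one of 0.30 (camera adjusted p = 0.00651, adjusted p = 0.335 with an estimated correlation) and oxidative phosphorylation genes 0.21 (camera adjusted p = 0.00552, adjusted p = 0.417 with an estimated correlation), with 0 called in either. Jun rose by 1.63 among 15 stress genes (2 over the list alone). The median was 1.05 (camera adjusted p = 0.0201, adjusted p = 0.417 with an estimated correlation). T cell markers were lower beside these groups, with a median of -1.56 and 0 of 11 called (2 over the list alone; camera adjusted p = 0.00651, adjusted p = 0.335 with an estimated correlation). Neutrophil markers had a median of 2.57 with 0 of 13 called and did not pass as a list (camera adjusted p = 0.201), nor did erythroid markers (median -1.64, 0 of 7 called, camera adjusted p = 0.0636). Xist exceeded 10 CPM in 3 of 4 MMSET and 2 of 4 Control(M) libraries, and the Y-linked Ddx3y exceeded 1 CPM in 0 of 4 and 2 of 4. MMSET 2 had neither, so Xist as a covariate cannot fully describe this imbalance. Its part in the MMSET calls was not weighed. DESeq2 called 745 genes (466 higher, 279 lower), limma voom 80 (47 and 33), a fit of all 36 libraries 57 (28 and 29) and a fit of the 2 groups 27 (18 and 9). The count was 65, 57 and 59 without Control(M) 1, 3 and 4, and 187, 52 and 42 without MMSET 1, 2 and 3.

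Ikk2ca(M) also differed from Control(M) in 100 genes, 78 higher and 22 lower, 75 by at least 2-fold. Elf3 rose by 7.23 (SE 0.860, adjusted p = 0.000507), Slc7a11 by 6.90, Ncan by 6.04 (2.52 ± 1.61 to 167 ± 75.0 CPM), Tgm2 by 5.44, Arrdc4 by 4.65, the IKK-related kinase Ikbke by 3.67, Cdkn1a by 3.11 and Csn3 by 2.75. The named falls were Ighg2c, an IgG heavy chain constant region (-5.35), H2-Aa (-4.16), Fcmr (-3.47), the phosphatase Ppm1h (-2.62), the transcription factors Ets1 (-2.31) and Irf8 (-2.06), Ctse (-2.22) and the translation regulator Cpeb2 (-1.88).

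NF-kB genes rose in 6 of 49 and fell in 0 (10 and 0 over the list alone), with Ebi3, a subunit shared by 2 interleukin-12 family cytokines, at 1.79, Icam1 at 2.44 (209 ± 59.9 against 38.6 ± 21.7 CPM), Tnip1 at 1.27 and Relb at 1.29. The list's median was 0.41 (camera adjusted p = 0.000139, adjusted p = 0.265 with an estimated correlation). Class I and immunoproteasome genes rose in 5 of 15 (9 over the list alone), including Tap2 (0.82), the peptide-loading chaperone Tapbp (0.62), Psme1 (0.70) and Psmb8 (0.67). As a list they had a median of 0.63 (camera adjusted p = 2.7e-08, adjusted p = 0.265 with an estimated correlation). In the class II list H2-Aa fell while Cd74 rose by 1.02, and 9 fell and 1 rose over the list alone. These genes had a median of -2.66 (camera adjusted p = 0.000104, adjusted p = 0.265 with an estimated correlation), and the list's mean lay below all Control(M) libraries in 2 of 4 Ikk2ca(M) libraries. Of 26 B cell genes Ly6d rose by 0.95 and Fcmr fell (3 fell and 1 rose over the list alone). Over the list the median was -1.27 (camera adjusted p = 0.000247, adjusted p = 0.265 with an estimated correlation). Of 19 p53 targets, Cdkn1a, Zmat3 (1.87), Btg2 (0.93) and Ccng1 (0.95) rose (9 rose and 2 fell over the list alone). The list had a median of 0.81 (camera adjusted p = 0.000411, adjusted p = 0.265 with an estimated correlation). Oxidative phosphorylation genes had 0 of 31 called and 8 higher over the list alone, with the complex I gene Ndufb9 at 114 ± 11.8 against 74.3 ± 14.3 CPM. Its members had a median of 0.34 (camera adjusted p = 1.13e-06, adjusted p = 0.265 with an estimated correlation). Interferon-stimulated genes had 0 of 29 called and 1 higher over the list alone, with Igtp at 142 ± 43.6 against 51.3 ± 3.57 CPM. Their median was 0.74 (camera adjusted p = 0.000411, adjusted p = 0.284 with an estimated correlation). Xist exceeded 10 CPM in 4 of 4 Ikk2ca(M) libraries. DESeq2 called 652 genes (370 higher, 282 lower) and limma voom 233 (116 and 117), and the count was 56 without Control(M) 3 and 44 and 46 without Ikk2ca(M) 2 and 3.

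With MMSET and Ikk2ca together, 1065 genes differed from Control(M), 539 higher and 526 lower, 773 by at least 2-fold. The named rises were Slc7a11 (24.5 ± 10.3 CPM, log2 fold change 9.86, adjusted p = 5.71e-07), the germ cell protein gene Tex101 (32.1 ± 34.2 CPM), Elf3 (9.64, to 53.6 ± 31.1 CPM), Ifi44 (9.04), Ly6i (7.66, to 2492 ± 1910 CPM), Fam174b (7.58), Rhox4b (6.91) and Ncan (6.78). The inhibitory receptor Btla fell from 23.6 ± 11 to 0.00537 ± 0.0132 CPM and the chitinase-like Chil3 from 10.3 ± 3.62 to 0.0156 ± 0.0250. Other falls included Cd79a (-7.56), H2-Ab1 (-7.39), the antimicrobial peptide gene Camp (-6.46) and the class II loading gene H2-DMb2 (-6.23).

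Interferon-stimulated genes rose in 14 of 29 and fell in 0 in MMSET-Ikk2ca (21 and 0 over the list alone), with a median of 2.26 (camera adjusted p = 7.35e-14, adjusted p = 0.0371 with an estimated correlation). Among them the apoptosis factor Xaf1 rose by 2.26 and Igtp by 1.99. NF-kB genes rose in 15 of 49 and fell in 3 (21 and 5 over the list alone), with Icam1 at 2.60, Tnfaip3 at 2.85, Relb at 1.63 (SE 0.228, adjusted p = 0.000283) and Ebi3 at 1.37. The median was 0.53 (camera adjusted p = 0.00019, adjusted p = 0.213 with an estimated correlation). Class I and immunoproteasome genes rose in 10 of 15 and fell in 0 (15 and 0 over the list alone), with H2-D1 at 1.28, H2-K1 at 1.02, Psme2 at 0.98 and Tapbp at 0.68. The list's median was 0.81 (camera adjusted p = 1.59e-09, adjusted p = 0.0754 with an estimated correlation). Of 19 p53 targets, 6 rose and 1 fell (9 and 2 over the list alone), with Cdkn1a at 59.6 ± 11 against 3.76 ± 2.28 CPM (3.99, adjusted p = 0.000338), Zmat3 at 1.85, Ccng1 at 0.91 and the pro-death gene Bbc3 at 1.12. As a list they had a median of 1.12 (camera adjusted p = 0.000316, adjusted p = 0.0591 with an estimated correlation). DNA replication genes rose in 3 of 31, among them Fen1 (0.66) and Tk1 (1.10), both over all genes and over the list alone. These genes had a median of 0.52 (camera adjusted p = 0.0323, adjusted p = 0.523 with an estimated correlation). Of the D-type cyclin and RB genes Cdkn1a rose, while Cdkn2c (-2.03) and Cdk6 (-7.29) fell (camera adjusted p = 0.801).

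B cell identity genes fell in 12 of 26 and rose in 1 (16 and 2 over the list alone). Over the list the median was -2.92 (camera adjusted p = 2.06e-08, adjusted p = 0.0545 with an estimated correlation). Besides Cd79a (1.91 ± 1.47 against 359 ± 28.4 CPM, SE 0.71, adjusted p = 1.83e-05), Ebf1 went from 9.59 ± 3.66 to 0.00502 ± 0.0123 and the kinase Blk from 14.6 ± 9.56 to 0.0107 ± 0.0263 CPM. Class II genes fell in 7 of 10 (9 over the list alone), with H2-Aa at -6.14 and H2-Eb1 at -3.35, while Cd74 rose by 1.43 to 10840 ± 2380 CPM. The list had a median of -4.74 (camera adjusted p = 9.15e-07, adjusted p = 0.105 with an estimated correlation). Plasma cell identity genes fell in 8 of 27 and rose in 2 (9 and 3 over the list alone). Its members had a median of -0.47 (camera adjusted p = 0.00143, adjusted p = 0.0591 with an estimated correlation). Jchain fell by 3.45, from 32760 ± 4220 to 3002 ± 1260 CPM (adjusted p = 0.000623). Also lower were Mzb1 (-4.44), Tnfrsf17 (-2.01), which encodes the survival receptor BCMA, and the elongation factor Ell2 (-0.90). Adhesion and migration genes fell in 10 of 27 and rose in 2 (17 and 2 over the list alone). Their median was -1.07 (camera adjusted p = 3.66e-06, adjusted p = 0.0591 with an estimated correlation). In that list the egress receptor S1pr1 went from 10.9 ± 12.5 to 0.00250 ± 0.00611 and Cxcr3 from 6.49 ± 3.42 to 0.00250 ± 0.00611 CPM, Klf2 fell by 6.46, and the endothelial and leukocyte adhesion gene Pecam1 rose by 2.04. Mitochondrially encoded genes fell in 9 of 13 (13 over the list alone), with mt-Nd2 at -1.06, mt-Nd5 at -0.79, mt-Nd4 at -0.76 and mt-Nd6 at -0.75 (median -0.64, camera adjusted p = 4.07e-08, adjusted p = 0.118 with an estimated correlation).

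Immune interaction ligands rose in 5 of 19 and fell in 2 (7 and 2 over the list alone; median 0.50 and mean -0.46, camera adjusted p = 0.274), with Lgals9 at 1.73, the don't-eat-me signal Cd47 at 1.10, Cd48 at -2.02 and Cd200 at 0.00236 ± 0.00578 against 10.4 ± 2.32 CPM. Secretory pathway genes rose in 5 of 31 (5 over the list alone; camera adjusted p = 0.225), among them Derl1 (0.73), the asparagine synthetase Asns (0.78), Selenos (0.47) and Sec61a1 (0.48). Stress genes rose in 3 of 15, Jun (1.77), Dusp1 (2.01) and Atf3, at 2.71 ± 2.12 against 0.00807 ± 0.00932 CPM (4 rose and 1 fell over the list alone; camera adjusted p = 0.357). Immunoglobulin constant regions had a median of -0.76 with 0 of 12 called, Igkc standing at 109700 ± 61200 against 228700 ± 36600 CPM (camera adjusted p = 0.0108, adjusted p = 0.0815 with an estimated correlation). Igkc made up 16.4% to 97.3% of light chain constant reads in single MMSET-Ikk2ca libraries. The lambda gene Iglc1 went the other way, with 32526993 reads over 6 libraries against 2131019 over 4 of Control(M). Neutrophil markers were lower beside these groups, with Camp, S100a8 (-4.77) and Mmp8 (-7.04) the 3 of 13 that fell (7 over the list alone). The median was -4.26 (camera adjusted p = 3.35e-05, adjusted p = 0.231 with an estimated correlation). T cell markers had a median of -1.78 with 0 of 11 called (2 over the list alone; camera adjusted p = 0.01, adjusted p = 0.245 with an estimated correlation). Of 14 monocyte and macrophage markers the complement gene C1qb rose by 2.5 and Ccr2 and Lyz2 (-5.38) fell (2 and 3 over the list alone; camera adjusted p = 0.137). Erythroid markers had a median of -3.42 with 1 of 7 risen and did not pass as a list (camera adjusted p = 0.0605). DESeq2 called 2196 genes and limma voom 1683 (782 higher, 901 lower), a fit of all 36 libraries gave 535 higher and 756 lower, and the count was 689 without Control(M) 3.

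Against the single transgenes, MMSET-Ikk2ca differed from Ikk2ca(M) in 148 genes (66 higher, 82 lower) and from MMSET in 244 (99 higher, 145 lower). The balance against Ikk2ca(M) depended on the fit, with 108 higher and 62 lower with only the 2 groups compared, and 70 and 159 with all 36 libraries. Against MMSET it was 61 higher and 47 lower with only the 2 groups compared, and 143 and 236 with all 36 libraries. Xist exceeded 10 CPM in 3 of 6 MMSET-Ikk2ca libraries, 4 of 4 of Ikk2ca(M) and 3 of 4 of MMSET. Ddx3y exceeded 1 CPM in 3 of 6, 0 of 4 and 0 of 4. With Xist as a covariate the counts were 64 against Ikk2ca(M) and 111 against MMSET, and with the replicate number as a block 74 and 111. Over Ikk2ca(M), Ifi44 rose by 6.69, Nsd2 by 6.35, Ighg2c by 5.02 and Ly6i by 4.87, and Btla and Chil3 were among the falls. Over MMSET, Ly6i rose by 7.27, the interferon-induced chemokine Cxcl10 by 4.83, Elf3 by 3.72 and Ncan by 3.44, and Chil3, Btla and Camp (-8.27) were among the falls. Interferon-stimulated genes rose in 4 of 29 over Ikk2ca(M) (13 over the list alone). The list's median was 1.16 (camera adjusted p = 2.46e-10, adjusted p = 0.0962 with an estimated correlation). They rose in 5 over MMSET (11 over the list alone). As a list they had a median of 1.60 (camera adjusted p = 3.92e-10, adjusted p = 0.0622 with an estimated correlation). Mitochondrially encoded genes fell in 5 of 13 against Ikk2ca(M) (13 over the list alone). These genes had a median of -0.65 (camera adjusted p = 9.48e-12, adjusted p = 0.131 with an estimated correlation). They fell in 10 against MMSET (12 over the list alone). Over the list the median was -0.68 (camera adjusted p = 2.24e-13, adjusted p = 0.0622 with an estimated correlation). NF-kB genes rose in 7 of 49 and fell in 1 against MMSET (17 and 3 over the list alone). The list had a median of 0.54 (camera adjusted p = 2.86e-06, adjusted p = 0.135 with an estimated correlation). Neutrophil markers fell in 5 of 13 against MMSET (11 over the list alone). Its members had a median of -6.84 (camera adjusted p = 1.05e-10, adjusted p = 0.0954 with an estimated correlation), next to 2.57 in MMSET and -4.26 in the pair against Control(M). Immunoglobulin constant regions had a median of 0.00 but a mean of -0.76 against MMSET, and the test pointed down (camera adjusted p = 0.00397, adjusted p = 0.0622 with an estimated correlation). Against Ikk2ca(M) the count was 89 and 76 without Ikk2ca(M) 1 and 4, and 93 and 239 without MMSET-Ikk2ca 3 and 4. Against MMSET it was 138 and 160 without MMSET 1 and 2, and 124 to 154 without MMSET-Ikk2ca 1, 2, 3 or 6.

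The interaction in cohort M passed in 15 genes, 3 above and 12 below the sum of the single effects. DESeq2 called 443, 204 above and 239 below, and limma voom 33, 8 and 25. With the replicate number as a block 3 genes passed, all below, and 6 passed both with all 36 libraries (1 above, 5 below) and with Xist as a covariate (2 and 4). St8sia4 lay above it (1.78, SE 0.264, adjusted p = 0.00777): it fell by 1.36 in MMSET and by 0.95 in Ikk2ca(M), and stood at -0.53 in the pair (adjusted p = 0.0711). Slc7a11 (-5.60), the histone mark reader Zcwpw1 (-4.85), the steroid dehydrogenase Hsd3b7 (-2.96, SE 0.362, adjusted p = 0.0019) and Ccnd2 (-2.40) lay below it. Hsd3b7 rose by 2.83 in MMSET, by 2.36 in Ikk2ca(M) and by 2.24 in the pair. Neutrophil markers gave a median interaction of -7.02 with 0 called (9 lower over the list alone; camera adjusted p = 2.69e-06, adjusted p = 0.396 with an estimated correlation). It includes the higher median in MMSET, since medians against Control(M) were 2.57 in MMSET, -0.09 in Ikk2ca(M) and -4.26 in the pair. Mitochondrially encoded genes gave -0.69 with 0 called (11 lower over the list alone; camera adjusted p = 5.56e-09, adjusted p = 0.383 with an estimated correlation). Without Control(M) 1, 3 and 4 the interaction count was 5, 4 and 9, without MMSET 1 and 2 it was 31 and 8, without Ikk2ca(M) 2 it was 6, and without MMSET-Ikk2ca 2 and 4 it was 4 and 25.

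**Figure D3:**
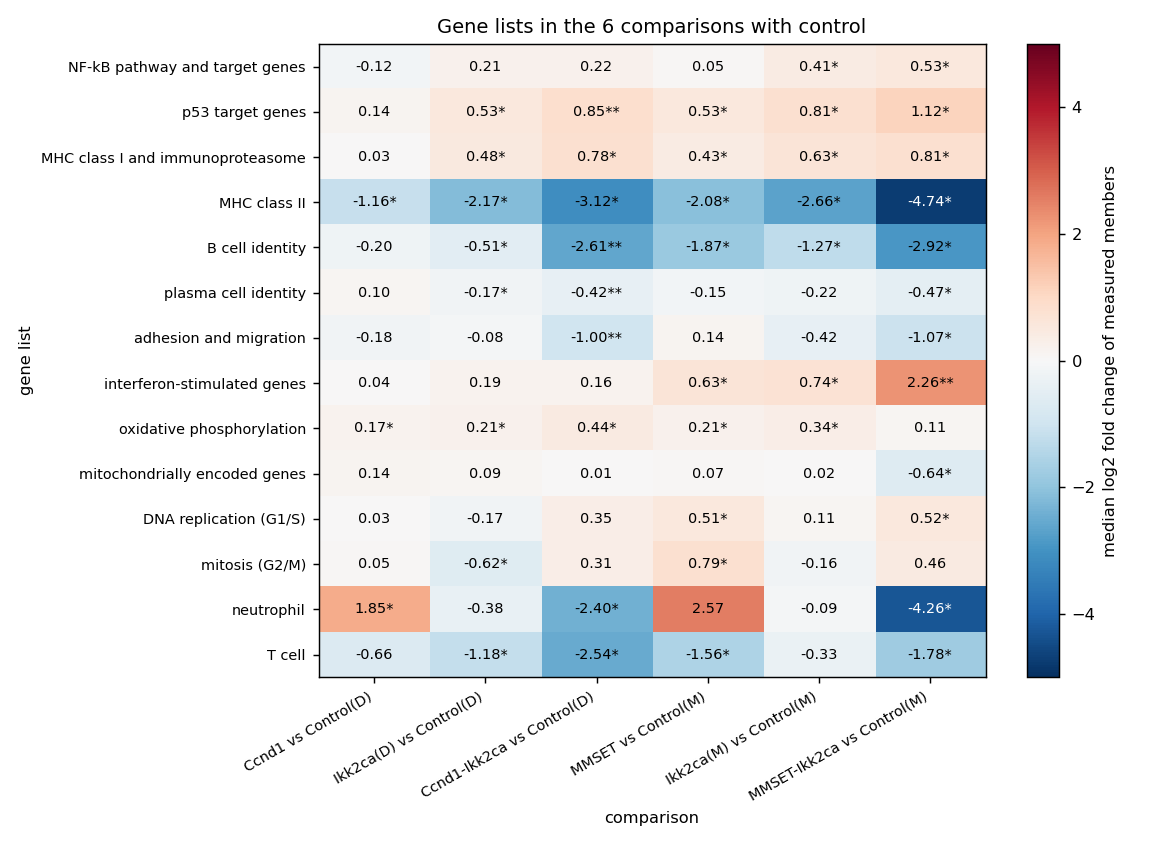
Median log2 fold change of the measured members of 14 gene lists in the 6 comparisons of a transgenic group with its control. There, 1 asterisk marks a camera adjusted p under 0.05 with the preset correlation and 2 asterisks mark a call that held with an estimated correlation as well. Class II medians ran from -1.16 in Ccnd1 to -4.74 in MMSET-Ikk2ca, and the interferon-stimulated median was 2.26 in MMSET-Ikk2ca and 0.16 in Ccnd1-Ikk2ca.

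Both cohorts contain an Ikk2ca group and a pair with its own control libraries, which allowed the calls to be compared over the 14562 genes tested in both. The Ikk2ca groups shared 18 higher genes of 61 and 78, where 0.327 would be shared by chance (Fisher's exact test, one-sided, adjusted p = 3.52e-27), and 2 lower genes of 6 and 21 (chance 0.00865, adjusted p = 4.44e-05). The shared rises were Ncan, Elf3, Relb, Tnip1, Icam1, Ikbke, Cdkn1a, Ccng1, Cyba, Tmem176a, Abcg1, Stambpl1, Scd2, Ifi211, Gpm6a, Ly6d, Ly6a and Gpx4, and the shared falls Ctse and Sat1. Xist-positive libraries were more frequent in both Ikk2ca groups than in their controls. With Xist as a covariate, 3 and 59 genes were higher and 1 was shared (chance 0.0122, adjusted p = 0.0242), and 0 and 15 were lower by edgeR. The 18 shared rises kept their sign in both cohorts, with median ratios of the log2 fold changes with and without the covariate of 0.901 in cohort D and 1.03 in cohort M. The pairs shared 245 higher genes of 885 and 500 (chance 30.4, adjusted p = 2.39e-169) and 223 lower genes of 781 and 523 (chance 28.0, adjusted p = 7.89e-150), with 1 gene called in opposite directions each way. With Xist as a covariate the pairs shared 204 higher and 217 lower genes. Ccnd1 and MMSET shared 0 called genes with 1 and 63 higher (adjusted p = 1) at the edgeR threshold. The 1 gene was Ccnd1 itself, so this test had almost no room to find an overlap and decides nothing. Genes are not independent replicates, and these tests count them as such.

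The direct tests between cohorts called few genes. Control(M) exceeded Control(D) in 7 genes of 17116, among them Large2 (2.65, 10.3 ± 4.41 against 1.65 ± 0.581 CPM), the membrane glycoprotein Gpm6a (1.57), the zinc finger gene Hivep3 (1.41) and Cgrrf1 (1.10). The balance between controls depended on the fit, with 297 higher and 162 lower by DESeq2, 4 and 5 by limma voom, and 3 and 3 with only the groups that enter. The Ikk2ca effect differed between cohorts in 0 genes with edgeR, where 1079 had an unadjusted p under 0.05, DESeq2 called 263 and limma voom 1. The MMSET effect differed from the Ccnd1 effect in 7 genes, among them Slc7a11 (10.39), Nsd2 (8.28) and Ccnd1 (-7.10). The effect of the pair differed in 30 genes, 10 higher in cohort M (Nsd2 7.78, the macrophage gene Mpeg1 4.12, the protease Napsa 2.24 and the interferon regulator Irf7 1.87) and 20 lower (Ccnd1 -9.86, the semaphorin receptor Nrp2 -6.61, H2-Eb2 -6.51 and the formin Fmnl1). Fmnl1 had 1 read in MMSET-Ikk2ca and 4410 in Control(M), and 1654 in Ccnd1-Ikk2ca and 9066 in Control(D). The balance for the pair was 66 higher and 72 lower with limma voom. Irf7 fell by 0.84 in Ccnd1-Ikk2ca and rose by 1.03 in MMSET-Ikk2ca. Interferon-stimulated genes were higher as a set in the effect of the pair in cohort M (2 of 29 called, 10 over the list alone). Their median was 1.42 (camera adjusted p = 4.22e-12, adjusted p = 0.00943 with an estimated correlation). Mitochondrially encoded genes were lower (0 of 13 called, 8 over the list alone). The median was -0.72 (camera adjusted p = 2.49e-09, adjusted p = 0.338 with an estimated correlation). Leaving out 1 library moved the count between controls by over 1.5 times in 26 of 36 cases. That between the MMSET and Ccnd1 effects moved in 16 of 36, that for Ikk2ca in 1 and that for the pair in 4.

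Plasma cells of many clones use many heavy chain variable genes, while 1 expanded clone uses 1. The most used IGHV gene took 8.04% ± 2.39 of IGHV reads in Control(D), 7.73% ± 3.59 in Ccnd1, 35.3% ± 37.3 in Ikk2ca(D) and 42.0% ± 17.3 in Ccnd1-Ikk2ca. In cohort M it took 16.7% ± 9.49 in Control(M), 28.0% ± 19.8 in MMSET, 42.9% ± 17.7 in Ikk2ca(M) and 44.5% ± 18.7 in MMSET-Ikk2ca. Exact two-sided permutation tests against the control gave p = 0.00952 for Ccnd1-Ikk2ca, the smallest that 6 against 4 libraries allow, and p = 0.0286 for MMSET-Ikk2ca, p = 0.0571 for each Ikk2ca group, p = 0.429 for MMSET and p = 0.8 for Ccnd1. After adjustment over these 6 tests none passed, with adjusted p = 0.0571 for Ccnd1-Ikk2ca and 0.0857 for MMSET-Ikk2ca and both Ikk2ca groups. With shares of TPM in place of reads, both pairs and both Ikk2ca groups passed (adjusted p = 0.0429 each by exact permutation), and MMSET and Ccnd1 did not (0.0686 and 0.429). With the most used IGKV gene in place of IGHV no group passed (adjusted p = 0.0571 for Ccnd1-Ikk2ca and both Ikk2ca groups, 0.0857 for MMSET-Ikk2ca, 0.24 for MMSET and 0.914 for Ccnd1). The difference for Ikk2ca(D) was 27.2 percentage points and 8.90 without Ikk2ca(D) 1, and for MMSET it was 11.3 and 1.61 without MMSET 3. Igha, the IgA constant region, made up 56.6% ± 19.6 of heavy chain constant reads in Control(D), 56.4% ± 29.9 in Ccnd1, 32.1% ± 20.3 in Ikk2ca(D) and 23.2% ± 20.8 in Ccnd1-Ikk2ca. Ighm, for IgM, made up 22.6% ± 16.8 in Control(D) and 56.9% ± 22.5 in Ccnd1-Ikk2ca. Ighm led in cohort M with 69.9% ± 8.19 in Control(M), 68.5% ± 17.0 in MMSET, 84.4% ± 8.94 in Ikk2ca(M) and 54.3% ± 32.3 in MMSET-Ikk2ca. The lowest adjusted p over 18 isotype tests by exact two-sided permutation was 0.24.

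**Figure D4:**
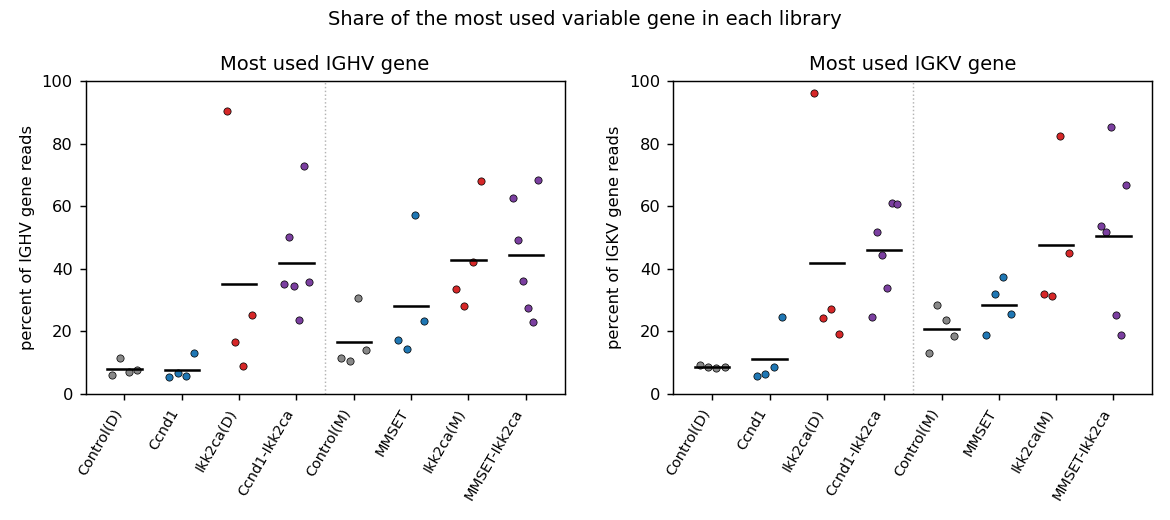
Percent of IGHV reads (left) and of IGKV reads (right) that came from the most used gene of each kind in each of the 36 libraries, by group. Points are libraries and bars are group means. The IGHV share averaged 8.04% in Control(D) and 16.7% in Control(M), and 35.3% to 44.5% in the 4 groups with Ikk2ca.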

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

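The tests of other cell types' markers for the interferon-stimulated genes, of the splits for Ccnd1 against Control(D), of the spread in the splits for differences of effects and with Xist as a covariate were chosen after results had been seen. Among 80 groups of values, 6 held 1 library far from the others, where chance gives about 1 in 20 groups, or 4. Ikk2ca(D) 4 had 97.6 M reads against 63.5 to 68.2 in the others. MMSET 4 had 0.716% mitochondrial reads against 0.883% to 0.897%. Ccnd1 stood at 3.54 CPM in Ikk2ca(D) 3 against 0.556 to 0.730, and at 0.947 in Control(M) 3 against 0.0159 to 0.144. Ikbkb stood at 71.8 CPM in Ikk2ca(M) 3 against 50.7 to 53.1, and Igha made up 13.8% of heavy chain constant reads in that library against 0.182% to 1.01%.

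Tests of a difference between effects called 4 genes and 7 gene lists for the interaction in Ccnd1-Ikk2ca, and 15 genes and 4 lists for that in MMSET-Ikk2ca, where camera in limma called 0 of the lists in either with an estimated correlation. Between cohorts they called 7 genes and 5 lists for the MMSET against the Ccnd1 effect, and 30 genes and 4 lists for the effect of the pair, where 0 and 1 of these lists passed with an estimated correlation.

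Lower MHC class II and B cell genes in the pairs, with both lists' means below all controls in 6 of 6 libraries of each, were weighed first. Across the 18 libraries of cohort D, deviations of both lists from their group means correlated (Pearson r = 0.666, 95% interval 0.234 to 0.879, two-sided permutation p = 0.00293, adjusted p = 0.00586; Spearman rho = 0.761, permutation p = 0.00078; r = 0.671 without the 2 farthest libraries), and in cohort M r was 0.798 (0.483 to 0.93, permutation p = 0.00897, adjusted p = 0.00897 over 2 tests; rho = 0.645, permutation p = 0.0143; r = 0.626 without the 2 farthest). Fewer B cells among sorted cells or a joint change within plasma cells would give this, so r cannot separate them, and both stay open. The CD138 and TACI gate would remove B cells, and 1 of the 28 B cell genes is also in another list. Xist as a covariate left the log2 fold changes at a median ratio of 0.999 (quartiles 0.994 to 1.02) in Ccnd1-Ikk2ca, which argues against uneven Xist-positive libraries as the cause there. In MMSET-Ikk2ca the shares were equal (3 of 6 against 2 of 4, by Xist and by Ddx3y), which argues against uneven shares there. With equal shares the ratio of 0.993 (0.941 to 1.03) itself decides nothing. The B cell genes fell unequally in MMSET-Ikk2ca, with Cd79a, scaled over all 36 libraries, at 1.87 ± 1.45 against 348 ± 27.1 CPM and Cd79b at 142 ± 30.9 against 224 ± 28.6, and others went up: Ly6d and Cd74 rose in both pairs, and Fcer2a stood at 40 ± 29.9 against 0.898 ± 1.25 CPM in MMSET-Ikk2ca and 10.1 ± 14.4 against 0.678 ± 1.3 in Ccnd1-Ikk2ca without passing, which fewer B cells alone would not give, so a change within the plasma cells may contribute, and it was not tested.

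Higher interferon-stimulated genes in MMSET-Ikk2ca were weighed second, with the list's mean above all controls in 6 of 6 libraries, as in 4 of 4 of MMSET and 3 of 4 of Ikk2ca(M). Markers had a median log2 fold change of -4.26 for neutrophils (quartiles -4.78 to -2.36) and -1.78 for T cells (-4.11 to -1.16), which argues against these cells as the source, and with each library left out the list's median log2 difference stayed between 2.11 (without Control(M) 4) and 2.59, which argues against 1 library. Markers of monocytes and macrophages (-0.918, quartiles -1.53 to 0.441), NK cells (-0.896, -1.18 to 0.108) and dendritic cells (-0.777, -3.08 to 0.671) went both ways, with C1qb at 19.8 ± 10.1 against 3.5 ± 1.22 CPM and Lyz2 at 2.03 ± 2.67 against 84.8 ± 26.4 CPM, so these cells stay open as sources, although the CD138 and TACI gate would remove them (2 of 14, 0 of 8 and 2 of 10 genes of these lists are also in another list). Xist-positive libraries had equal shares in the groups (3 of 6 against 2 of 4), which argues against uneven shares as the cause. With equal shares the median ratio of 0.991 (quartiles 0.976 to 1) with Xist as a covariate itself decides nothing. An effect of the transgenes, single or combined, is a candidate explanation, and uneven exposure of the animals to infection stays open and was not tested.

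The genes called in the Ikk2ca groups were weighed next, since Xist exceeded 10 CPM in 4 of 4 libraries of each and in 1 of 4 Control(D) and 2 of 4 Control(M) libraries. With Xist as a covariate, the 67 genes of Ikk2ca(D) had a median ratio of 0.926 (quartiles 0.866 to 0.978) and 0 changed sign, while the median absolute log2 fold change went from 1.88 to 1.70 and the median SE from 0.331 to 0.370, and 3 genes stayed called. The calls ended with a larger SE and slightly smaller effects, and what made the SE larger was not tested. In Ikk2ca(M) the 100 genes had a median ratio of 1.02 (quartiles 0.964 to 1.07), and 65 stayed called as the median went from 1.64 to 1.58 and the SE from 0.274 to 0.303. The ratios argue against uneven Xist-positive libraries as the whole cause, and the effect of the transgene is a candidate explanation.

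Other splits of the same libraries were refitted to see whether chance can be excluded. It can for Ikk2ca(D) (67 genes against at most 4 in the other splits), MMSET (100 against 14) and Ikk2ca(M) (100 against 6), where 1 of 35 splits, the real one, called as many. It can with 1 of 40 splits for Ccnd1-Ikk2ca against Control(D) (1708 against 1), Ikk2ca(D) (65 against 1) and Ccnd1 (950 against 193) and for MMSET-Ikk2ca against Control(M) (1065 against 5), Ikk2ca(M) (148 against 2) and MMSET (244 against 4). For the interactions 1 of 40 splits called as many (4 against 2 in cohort D and 15 against 1 in cohort M), and for the difference between the pairs 1 of 30 (30 against 2), which decides nothing. These splits also mixed groups that differ by other effects, which raised the common coefficient of variation from 0.840 to at least 0.885 in cohort D, from 0.905 to at least 0.968 in cohort M and from 0.948 to at least 0.96 across cohorts. For Control(M) against Control(D), 1 of 30 splits called as many (7 against 2). This decides nothing, as edgeR called 0 with pairs limited to replicates 1 to 4 and 0 to 16 with each library left out. With all replicates limma voom called 9 and DESeq2 459. The shares were not adjusted over the 16 comparisons. For Ccnd1 against Control(D), 9 of 35 splits called as many (1 against 2), which concerns the number of genes and not Ccnd1 itself, at 253 to 381 CPM against 0.607 to 1.27. For the Ikk2ca difference the count of 0 by edgeR (1079 genes at unadjusted p under 0.05, 263 by DESeq2 and 1 by limma voom) is matched by any split, so 30 of 30 (at most 2 in the others) decides nothing. Chance cannot be excluded for the number of genes in the MMSET and Ccnd1 difference, where 3 of 30 splits called as many (7 against 22). There 1 split called several times the real count, which may point to a structure of the samples that was not tested.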

How the results depend on the processing

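Xist as a covariate, leaving out Y-linked genes with Xist, and singling out the fit without Ikk2ca(D) 1 were chosen after the data were seen. All other alternatives were chosen before. Over all alternatives, the 411 values of named genes were on the same side of the threshold in 11169 cases, lost the call in 1193, gained it in 156 and changed sign while called in 0. The 128 list calls held in 254 cases and were lost in 130. With an estimated correlation 14 of the 128 list calls remained, 1 of them the list of targeted genes, which its own transgenes fix. Replicate numbers paired libraries weakly at most. Same-number pairs correlated at a median of 0.012 (-0.024 to 0.088) in cohort D and 0.03 (-0.042 to 0.11) in cohort M. Other pairs had medians of -0.0038 and -0.0053. In the 2 cohorts 7 of 16 and 6 of 16 libraries correlated best with their own number, and no chance level was computed for these counts. With 2000 cells per library and 4 or 6 libraries per group, 32% to 42% of simulated 2-fold changes were recovered, so small changes are largely out of reach. The simulated changes were placed only in genes above a minimum mean CPM. Where a count below moved, the cause was not tested.

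With DESeq2 the counts were 142 for Ccnd1, 687 for Ikk2ca(D), 2806 for Ccnd1-Ikk2ca against Control(D), 485 against Ikk2ca(D), 2015 against Ccnd1 and 153 for the interaction. In cohort M, DESeq2 gave 745 for MMSET, 652 for Ikk2ca(M), 2196 for MMSET-Ikk2ca against Control(M), 807 against Ikk2ca(M), 922 against MMSET and 443 for the interaction, and across cohorts 459 between controls and 263, 363 and 561 for the Ikk2ca, single and pair differences. With limma voom they were 0 for Ccnd1, 127 for Ikk2ca(D), 116 and 1542 for Ccnd1-Ikk2ca against Ikk2ca(D) and Ccnd1, 2 for its interaction, 233 for Ikk2ca(M), 1683 and 572 for MMSET-Ikk2ca against Control(M) and Ikk2ca(M), 33 for its interaction, and 1, 14 and 138 for the differences between cohorts.

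With the replicate number as a block the counts were 2 for Ccnd1, 1017, 37 and 551 for Ccnd1-Ikk2ca against Control(D), Ikk2ca(D) and Ccnd1, 694, 74 and 111 for MMSET-Ikk2ca against Control(M), Ikk2ca(M) and MMSET, 3 for its interaction, 3 between controls and 1 for the single difference. With the pairs limited to replicates 1 to 4, they were 996, 16 and 544 for Ccnd1-Ikk2ca in the same order, 0 for its interaction, 639, 68 and 123 for MMSET-Ikk2ca, 0 between controls, 2 for the single and 17 for the pair difference. With all 36 libraries in 1 fit, they were 115 for Ikk2ca(D), 9 for Ccnd1-Ikk2ca against Ikk2ca(D), 0 for its interaction, 57 for MMSET, 229 and 379 for MMSET-Ikk2ca against Ikk2ca(M) and MMSET, and 6 for its interaction. With only the 2 groups compared, they were 5 for Ccnd1, 9 for Ccnd1-Ikk2ca against Ikk2ca(D), 27 for MMSET and 108 for MMSET-Ikk2ca against MMSET, and with only the groups that enter, 60 for the pair difference. With Xist as a covariate, they were 3 for Ikk2ca(D), 0 for the interaction in cohort D, 64 and 111 for MMSET-Ikk2ca against Ikk2ca(M) and MMSET, 6 for its interaction and 4 between controls. A transcript length offset gave 43 for Ccnd1-Ikk2ca against Ikk2ca(D), leaving out immunoglobulin genes 24 for the interaction in cohort M, and no low-count filter 4 between controls.

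At an adjusted p of 0.01 the cohorts shared 3 higher and 0 lower genes for Ikk2ca, and 72 higher and 53 lower for the pairs. With Xist as a covariate, they shared 1 higher and 0 lower genes for Ikk2ca. From TPM, the log2 fold change of Ccnd1 was 9.48 in Ccnd1 and 11.06 in Ccnd1-Ikk2ca, and that of Nsd2 in MMSET-Ikk2ca 7.54. With TPM shares, the most used IGHV gene passed the threshold in Ikk2ca(D) (difference 27.09 percentage points), Ccnd1-Ikk2ca (30.35), Ikk2ca(M) (31.4) and MMSET-Ikk2ca (28.02), each with adjusted p = 0.0429 by exact permutation. With the most used IGKV gene no group passed (lowest adjusted p = 0.0571).

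With each library left out in turn, the counts ranged from 1 to 3 (without Control(D) 4) for Ccnd1 and from 17 (Control(D) 2) to 120 (Ccnd1 4) for Ikk2ca(D). For Ccnd1-Ikk2ca they ranged from 984 (Control(D) 2) to 1844 (Ikk2ca(D) 1) against Control(D), from 15 (Ccnd1-Ikk2ca 4) to 120 (Ccnd1-Ikk2ca 2) against Ikk2ca(D) and from 410 (Ccnd1 1) to 1120 (Ikk2ca(D) 1) against Ccnd1, with 0 to 7 for its interaction. They ranged from 42 (MMSET 3) to 187 (MMSET 1) for MMSET and from 44 (Ikk2ca(M) 2) to 123 (MMSET 3) for Ikk2ca(M). For MMSET-Ikk2ca they ranged from 689 (Control(M) 3) to 1223 (MMSET-Ikk2ca 4) against Control(M), from 76 (Ikk2ca(M) 4) to 239 (MMSET-Ikk2ca 4) against Ikk2ca(M), from 124 (MMSET-Ikk2ca 1) to 362 (MMSET-Ikk2ca 4) against MMSET, and from 4 (Control(M) 3) to 31 (MMSET 1) for its interaction. Between cohorts they ranged from 0 (Control(D) 2) to 16 (Ccnd1 1) for the controls, from 0 to 1 (Control(D) 4) for the Ikk2ca difference, from 1 (Ccnd1 1) to 14 (MMSET 1) for the single difference and from 14 (Control(D) 2) to 41 (MMSET-Ikk2ca 4) for the pair difference.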

Other observations

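The test of the Igha gap between the controls, and the 8 measures it was adjusted over, were chosen after the gap was seen. In Ikk2ca(D) 1 a single pair of variable genes, Ighv11-2 and Igkv14-126, made up 90.3% of IGHV and 96.2% of IGKV reads. The same 2 genes made up 30.8% and 23.6% in Control(M) 3, 23.2% and 23.5% in MMSET 4, 22.9% and 17.6% in MMSET-Ikk2ca 5, 12.7% and 7.65% in Control(M) 4, 11.6% and 13% in Control(M) 1 and 11.3% and 11% in Ikk2ca(M) 1, and at most 7.60% and 7.91% in the other libraries. The kappa constant gene Igkc made up 64.7% ± 35.8 of light chain constant reads in MMSET-Ikk2ca (n = 6, 16.4% to 97.3%) and 94.8% ± 1.44 in Control(M) (n = 4). The effective number of IGHV genes averaged 36.6 in Control(D), 39.4 in Ccnd1, 13.8 in Ikk2ca(D), 5.65 in Ccnd1-Ikk2ca, 18.1 in Control(M), 9.22 in MMSET, 4.87 in Ikk2ca(M) and 4.84 in MMSET-Ikk2ca.

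Igha made up 56.6% of heavy chain constant reads in Control(D) and 15.2% in Control(M), a difference of 41.4 percentage points (exact two-sided permutation p = 0.0286, the smallest 4 against 4 allow). Of 8 immunoglobulin measures compared between the controls, 5 reached that p, and adjusted over the 8 it was 0.0457 for Igha, close to the threshold and for a gap picked from these values. Cohort and any difference in housing, age or sorting day coincide here, and these were not tested. Xist and the Y-linked Ddx3y were both near 0 in MMSET 2, at 1.71 and 0.0222 CPM.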
